A study of Pseudotaxus chienii and Amentotaxus argotaenia and Torreya grandis with 9 samples.

How the data were processed

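RNA-seq libraries of fresh twigs, wood and needles together, from P. chienii, A. argotaenia and T. grandis were analysed, with 3 libraries per species. Per the labels, total RNA was extracted with Trizol and libraries were prepared with standard Illumina protocols from plants aged 3 years. The deposited values are in TPM, a length-normalised unit with the same total in each library, in 1 table per library with 2 decimals. The unit was read from the values, since the file headers name none: each library summed to between 999890 and 999947, and low values shared no common step, so they are not CPM of whole reads. Trinity is named per the labels and the feature IDs; the assembly input, the quantifier, the versions and any filter are not given in the sources used here. All 9 tables list the same 88609 features in the same order, so the levels of all species refer to 1 list, and reads of one species may be assigned to a feature built from another. TPM keeps no depth, so the number of reads behind a value is unknown, no interval for counting error was computed, and count-based tests were not used.

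Species were taken from the sample titles and phenotypes from the labels. The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(TPM + 1), without further scaling, on the 75926 features with at least 1 TPM in at least 3 libraries. All 9 libraries entered 1 fit with species as the only term, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method. A feature was called changed at an adjusted p under 0.05 and at least 2-fold. Fold changes are on the log2(TPM + 1) scale and understate the change of low features. The comparisons were P. chienii against each other species and against the mean of both, and A. argotaenia against T. grandis. Features higher or lower in P. chienii than in both others had to pass both tests with the same sign. The overlap was set beside 20 simulations of unchanged groups sharing the P. chienii libraries and beside the product of independent lists. The named features were chosen by a rule set before the data were examined: per comparison, the 2 largest rises and the 2 largest falls among changed features with a mean of at least 10 TPM in the higher species and no overlap of the libraries, with ties by ID.

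A feature was detected in a species at 1 TPM or more in all 3 libraries. Correlations were Pearson's r on log2(TPM + 1). A component is the set of features whose IDs differ only in the gene number; TPM was summed over it, and 19211 of the 42956 components hold several features. Levels at features of another species were measured at features with a mean of at least 100 TPM in the source species and under 2% of that mean in both others. The detection, correlation and component tables were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

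The limma step was tested on simulated data for P. chienii against A. argotaenia with 75926 features, of which 200 were changed. It called 11.9% of those changed 2-fold, 62.7% of those changed 4-fold and 77.3% of those changed 8-fold, with 9 false calls. Features changed 2-fold lie on the fold limit of the call itself. In the real comparison 47535 features were called, which makes the adjusted p less strict than with 200 changed. The rates therefore show that the step works and do not give the sensitivity or false calls of the reported tests. Fixed lists of taxoid, flavonoid, lignin, hormone and other genes were to be tested with camera and fry; the feature IDs are not paired with gene names and no reference was used here, so none of these lists was tested and no gene is named.

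Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, features above 0 in all libraries compared, trimmed-mean scaling, quantile normalization, no intensity trend, only the species compared, the replicate number as a block, each library left out in turn, no minimum fold, at least 4-fold, detection limits of 0.1 and 5 TPM, Spearman correlation and correlation over features above 0 in all 9 libraries. Those chosen after seeing the data were leaving out the 3 libraries that stood apart, a term for these libraries, setting values under 2% of the highest species mean to 0, component sums with and without a value above 0 in all 9 libraries, and keeping the tested features as with all 9 libraries when a library is left out. The counts over features at 1 TPM or more in all 6 libraries compared were also chosen after seeing the data.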

Results

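Transcript levels measured by RNA-seq were analysed in fresh twigs, wood and needles together, of 3 trees of the yew family (Taxaceae). Pseudotaxus chienii is labelled as producing taxol, the diterpenoid anticancer compound of yews, and Amentotaxus argotaenia and Torreya grandis are labelled as not producing it. Each species had 3 libraries, 9 in all. The labels do not say whether the libraries of a species came from separate trees, so p-values measure only the spread between these samples, which may be technical. Every library was given in TPM, a length-normalised unit in which each library has the same total, over the same 88609 gene-level features of a Trinity transcript assembly, and the feature IDs are not paired with gene names. The design set the taxol-producing species against the others, and since only 1 species carries that label, phenotype and species cannot be separated. Sequencing depth is unknown, because TPM keeps no read count, so no counting interval is given.

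The number of features at 1 TPM or more ranged from 37701 in T. grandis replicate 3 to 46682 in A. argotaenia replicate 3. The species means were 40582 ± 2393 (SD, n = 3) in P. chienii, 45011 ± 2760 in A. argotaenia and 38747 ± 1065 in T. grandis. The 10 most abundant features held 7.01% ± 0.665 of the TPM in P. chienii (SD, n = 3), 10.97% ± 1.88 in A. argotaenia and 8.88% ± 1.14 in T. grandis. Of the 100 most abundant features, A. argotaenia and T. grandis shared 41, P. chienii and A. argotaenia 31, and P. chienii and T. grandis 28.

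Libraries of a species were closely related and libraries of different species were not. Across features, Pearson's r on log2(TPM + 1) averaged 0.914 within species, with a range from 0.879 to 0.955 over 9 pairs of libraries. The mean r was 0.429 between A. argotaenia and T. grandis, 0.216 between P. chienii and T. grandis and 0.160 between P. chienii and A. argotaenia. By Spearman the same means were 0.272, 0.0989 and 0.0184. These correlations run across features, which are not independent replicates. Features of one Trinity component, the cluster named by the ID without its gene number, were then summed, which gave 42956 components. After summing, the mean r was 0.623 between A. argotaenia and T. grandis, 0.509 between P. chienii and T. grandis and 0.454 between P. chienii and A. argotaenia. In each species 1 library stood apart from the other two. P. chienii replicate 1 correlated with the others at 0.900 and 0.911, T. grandis replicate 3 at 0.890 and 0.908, and A. argotaenia replicate 2 at 0.879 with replicate 1.

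**Figure D1:**
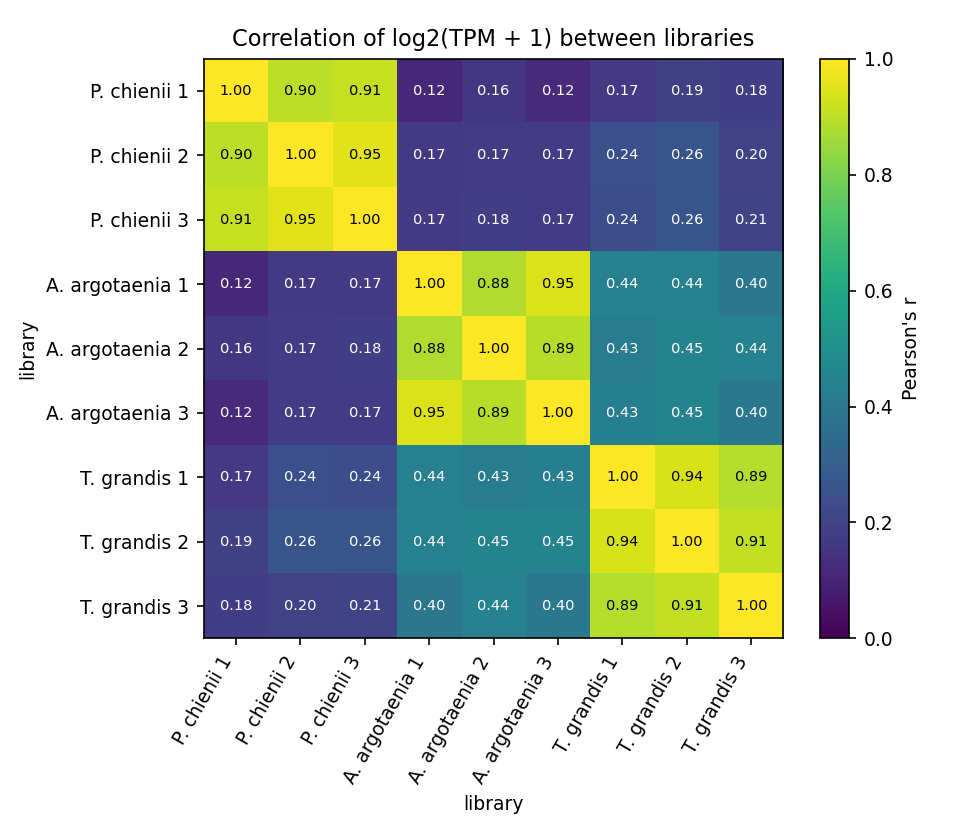
Pearson correlation of log2(TPM + 1) across 88609 features between each pair of the 9 libraries, on a color scale from 0 to 1. Pairs within a species lie between 0.879 and 0.955, and the mean between species is at most 0.429.

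Abundant features of one species were also listed at low levels in the libraries of the others. At features with a mean of at least 100 TPM in one species and under 2% of that mean in both others, the median level in a library of another species was between 0.0518% and 0.848% of the source species' mean. P. chienii replicate 2 held the features of A. argotaenia at a median of 0.848% of their level there, replicate 3 at 0.429% and replicate 1 at 0.0964%. T. grandis held them at 0.648%, 0.420% and 0.133% in replicates 1, 2 and 3. The levels below several of the fold changes reported here are of this size.

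**Figure D2:**
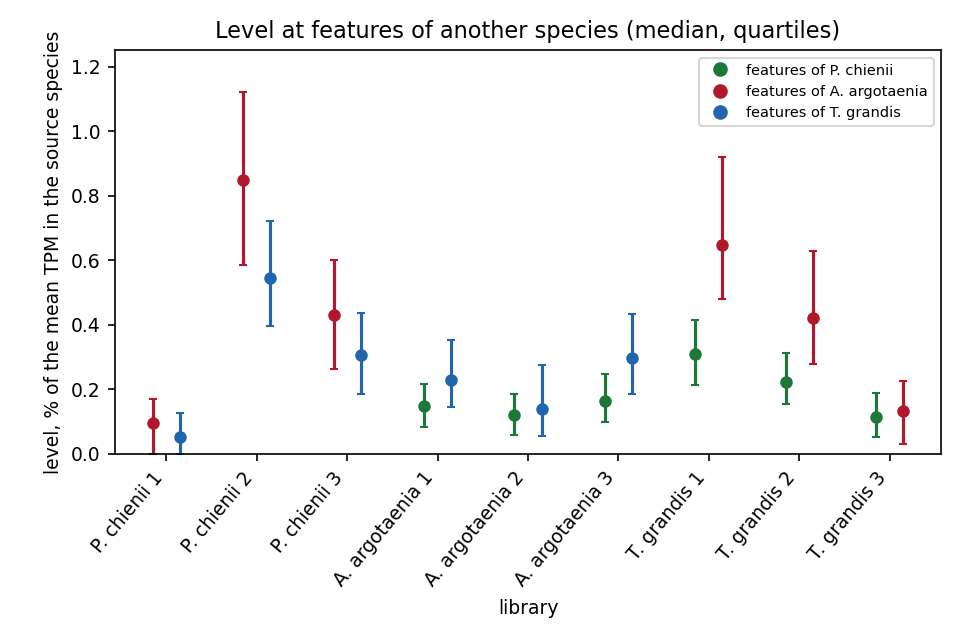
Level of each library at abundant features of another species, as a percentage of the mean TPM in that source species; points are medians over the features and bars run from the lower to the upper quartile. The medians lie between 0.0518% and 0.848%, and P. chienii replicate 1 holds the lowest.

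The comparison of P. chienii with A. argotaenia asked which features distinguish the taxol-producing species from a non-producing one. TRINITY_DN41305_c0_g4 stood at 9743 ± 2269 TPM (SD, n = 3) in P. chienii against 10.3 ± 2.42 TPM in A. argotaenia, a log2 fold change of 9.74 ± 0.34 (SE) on the log2(TPM + 1) scale, and rose with adjusted p = 7.73e-08 by limma. TRINITY_DN43857_c0_g2 also rose, from 2.95 ± 1.41 TPM in A. argotaenia to 3026 ± 1438 TPM in P. chienii, a log2 fold change of 9.51 ± 0.50 (SE; adjusted p = 4.83e-07, limma). The whole component of the second feature was at 3071 ± 1428 TPM in P. chienii and 3308 ± 2078 TPM in A. argotaenia. Different features of it thus held the level in each species, at overlapping totals. Counterparts assembled as separate features would give this too, and no sequences were compared. The component of TRINITY_DN41305_c0_g4, in contrast, was at 28.6 ± 19.2 TPM in A. argotaenia. TRINITY_DN48037_c1_g2 was at 3.19 ± 2.66 TPM in P. chienii and 1406 ± 648 TPM in A. argotaenia, with a log2 fold change of -8.47 ± 0.56 (SE; adjusted p = 1.85e-06, limma), and its component was at 473 ± 87.6 TPM and 1662 ± 770 TPM. TRINITY_DN40491_c0_g8 was at 8.75 ± 4.61 TPM in P. chienii and 3511 ± 2521 TPM in A. argotaenia, with a log2 fold change of -8.38 ± 0.54 (SE; adjusted p = 1.49e-06, limma), and its component was at 11.003 ± 6.15 TPM and 3632 ± 2550 TPM. The libraries of the species did not overlap at these features, but this was a condition for choosing them and adds no support. Chance alone gives it in 10% of features with 3 libraries against 3.

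In all, 47535 of 75926 tested features changed between P. chienii and A. argotaenia at an adjusted p under 0.05 and at least 2-fold. Of these, 22328 were higher and 25207 lower in P. chienii. In 83.1% of the changed features the lower species was under 1 TPM in all 3 libraries. Among the 13254 features at 1 TPM or more in all 6 libraries, 4901 changed, 2886 of them higher and 2015 lower in P. chienii. The median log2 fold change of those 13254 features was 0.15. After trimmed-mean scaling it was 0.00, with 2461 features higher and 2379 lower. That scaling centres features at 1 TPM or more in all 9 libraries, so a median near 0 follows largely from the method. Quantile normalization gave 2819 higher and 2261 lower. As component sums, 21186 of 39423 changed. The feature count was 14099 with a mean of at least 5 TPM and 10170 with features above 0 in all libraries compared. With 1 P. chienii library left out and the filter on low features applied anew, the count lay between 29356 and 29588 and at most 17.1% of them were higher in P. chienii, because features found in that species alone then no longer reached the filter; keeping the tested features as they were gave at least 46677. With 1 A. argotaenia library left out in the same way, 66.4% or more were higher in P. chienii, so the balance of higher against lower features in the full count depends on the filter. It also turned with the scale on the same 75926 features, from 47.0% higher with a pseudocount of 1 to 51.6% with a pseudocount of 5, where 12851 were higher and 12030 lower.

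**Figure D3:**
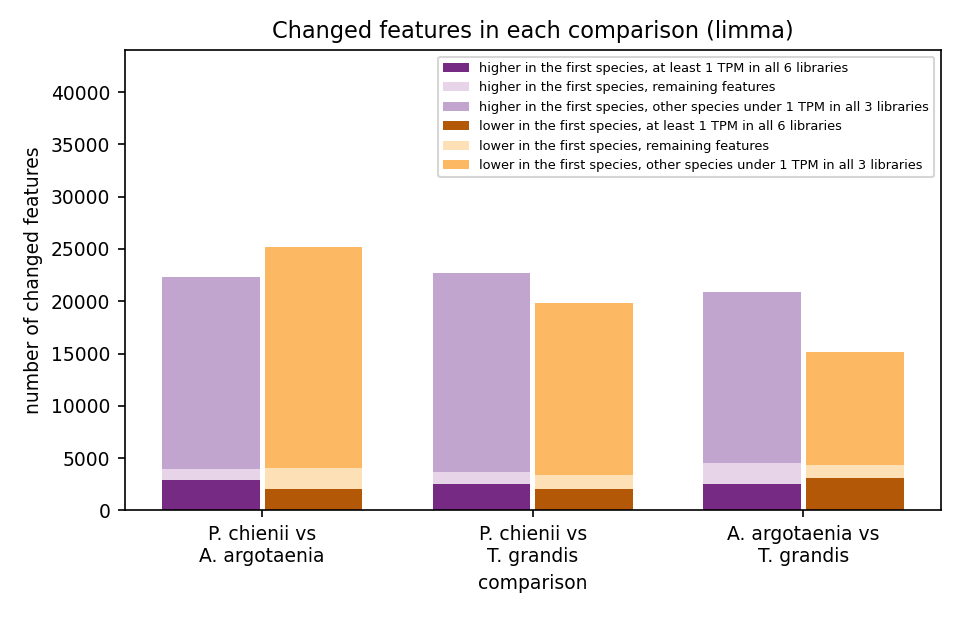
Number of changed features (limma, adjusted p under 0.05 and at least 2-fold) in each comparison of species; purple bars are features higher and orange bars features lower in the species named first, divided by the level in the other species. Features with the other species under 1 TPM in all 3 libraries make up 83.1%, 83.3% and 75.4% of the 3 comparisons from left to right.

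P. chienii was set against T. grandis, the other non-producing species, in the same fit. TRINITY_DN47640_c0_g1 rose from 1.54 ± 0.956 TPM (SD, n = 3) in T. grandis to 1721 ± 472 TPM in P. chienii, a log2 fold change of 9.43 ± 0.30 (SE; adjusted p = 4.98e-08, limma). It is the single feature of its component. TRINITY_DN41305_c0_g4, named above, also rose against T. grandis, where it stood at 16.4 ± 6.58 TPM, by a log2 fold change of 9.19 ± 0.34 (SE; adjusted p = 8.46e-08, limma). TRINITY_DN40080_c1_g6 was at 9.95 ± 6.71 TPM in P. chienii and 4477 ± 1405 TPM in T. grandis, with a log2 fold change of -8.86 ± 0.47 (SE; adjusted p = 5.10e-07, limma), and its whole component was at 12.7 ± 6.25 TPM and 4523 ± 1426 TPM. TRINITY_DN36656_c0_g7 was at 39.2 ± 33.5 TPM in P. chienii and 13352 ± 3360 TPM in T. grandis, with a log2 fold change of -8.87 ± 0.80 (SE; adjusted p = 1.31e-05, limma). Its component as a whole was higher in P. chienii, at 24050 ± 3213 TPM against 13474 ± 3362 TPM, levels given without a test.

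Between P. chienii and T. grandis 42560 of the 75926 features changed, 22734 higher and 19826 lower in P. chienii. The lower species was under 1 TPM in all 3 libraries in 83.3% of them. Of 12567 features at 1 TPM or more in all 6 libraries, 4538 changed, with 2516 higher and 2022 lower in P. chienii. The balance turned to 2188 higher and 2220 lower after quantile normalization, but stayed at 2330 higher and 2176 lower after trimmed-mean scaling. Component sums changed in 19081 of 39423 cases. The feature count was 23298 with a pseudocount of 5, 13885 with a mean of at least 5 TPM and 9576 with features above 0 in all libraries compared. Without 1 P. chienii library and with the filter applied anew, 24257 to 24426 features changed, at most 22.0% of them higher in P. chienii, against at least 41605 with the tested features kept. Without 1 T. grandis library and with the filter applied anew, 69.0% or more were higher in P. chienii.

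A. argotaenia and T. grandis, both labelled non-producing, were compared as 1 pair of species without the phenotype. How closely the species are related was not taken into account, so this pair is no baseline for the P. chienii counts. TRINITY_DN36656_c0_g2 was at 13751 ± 2464 TPM (SD, n = 3) in A. argotaenia and 48.9 ± 34.0 TPM in T. grandis, a log2 fold change of 8.44 ± 0.80 (SE; adjusted p = 2.61e-05, limma). TRINITY_DN36656_c0_g7, of the same component, was at 27.1 ± 14.3 TPM in A. argotaenia and 13352 ± 3360 TPM in T. grandis, a log2 fold change of -9.03 ± 0.80 (SE; adjusted p = 1.73e-05, limma). The component summed to 13858 ± 2456 TPM in A. argotaenia and 13474 ± 3362 TPM in T. grandis. TRINITY_DN36656_c0_g1, a feature singled out after its values were seen, held 99.5% of this component in P. chienii, while TRINITY_DN36656_c0_g2 held 99.2% of it in A. argotaenia and TRINITY_DN36656_c0_g7 held 99.1% in T. grandis. TRINITY_DN40491_c0_g8 rose to 3511 ± 2521 TPM in A. argotaenia from 8.06 ± 3.25 TPM in T. grandis, a log2 fold change of 8.42 ± 0.54 (SE; adjusted p = 2.57e-06, limma), and its component was at 3632 ± 2550 TPM and 787 ± 176 TPM. TRINITY_DN40905_c1_g5 was at 10.4 ± 7.02 TPM in A. argotaenia and 5340 ± 607 TPM in T. grandis, a log2 fold change of -9.03 ± 0.73 (SE; adjusted p = 9.92e-06, limma), and its component was at 1980 ± 1325 TPM and 7892 ± 566 TPM.

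**Figure D4:**
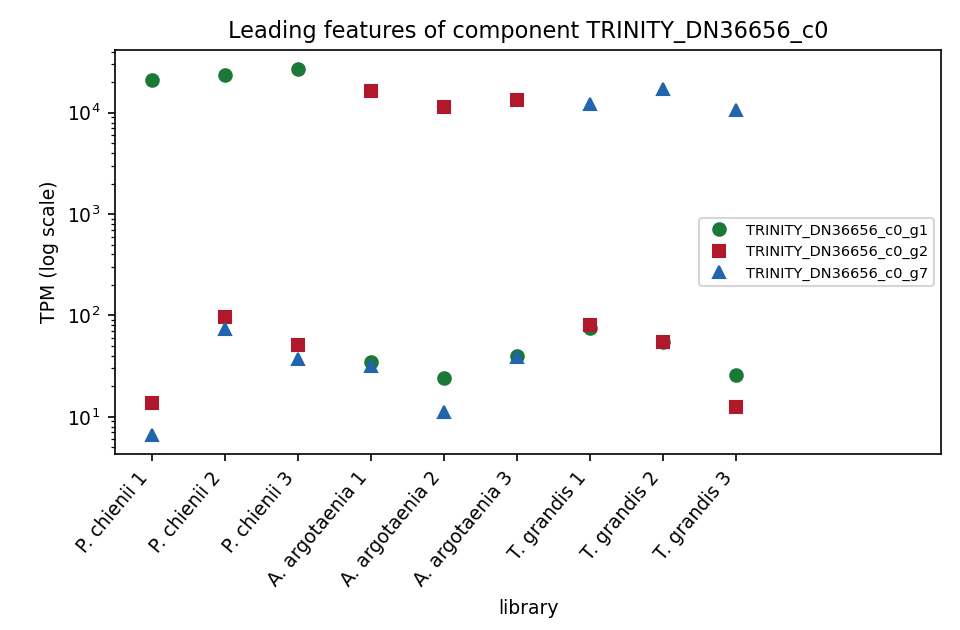
TPM of the 3 leading features of component TRINITY_DN36656_c0 in each of the 9 libraries, on a log scale, 1 point per feature and library. In every library the feature leading in its species lies at 10699 TPM or more and both other features lie at 95.9 TPM or less.

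The count for this pair was 36039 of 75926 features, 20858 higher and 15181 lower in A. argotaenia, and in 75.4% of them the lower species was under 1 TPM in all 3 libraries. Of 16902 features at 1 TPM or more in all 6 libraries, 5591 changed, 2546 higher and 3045 lower in A. argotaenia. Trimmed-mean scaling, which largely centres such features by design, gave 2816 higher and 2800 lower. Quantile normalization gave 2514 higher and 3272 lower. Component sums changed in 16671 of 39423 cases. The feature count was 16909 with a pseudocount of 5, 9966 with a mean of at least 5 TPM and 9772 with features above 0 in all libraries compared. With the filter applied anew, leaving out 1 A. argotaenia library gave 20621 to 22025 features, at most 31.7% of them higher in A. argotaenia, and leaving out 1 T. grandis library gave 25237 to 26088, at least 78.6% higher; keeping the tested features gave at least 35070.

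P. chienii was also compared with the mean of both non-producing species. The largest rises were those of TRINITY_DN41305_c0_g4, with a log2 fold change of 9.47 ± 0.29 (SE; adjusted p = 3.08e-08, limma), and TRINITY_DN47640_c0_g1, with 9.24 ± 0.26 (SE; adjusted p = 2.10e-08, limma). TRINITY_DN43094_c0_g2 was at 23.2 ± 17.3 TPM (SD, n = 3) in P. chienii, 5007 ± 338 TPM in A. argotaenia and 2927 ± 193 TPM in T. grandis, a log2 fold change of -7.62 ± 0.45 (SE; adjusted p = 9.46e-07, limma). The component of that feature summed to 4085 ± 126 TPM in P. chienii, 5033 ± 347 TPM in A. argotaenia and 2951 ± 191 TPM in T. grandis, so other features of it carried the P. chienii level. TRINITY_DN41386_c1_g1 was at 38.9 ± 8.26 TPM in P. chienii and 7218 ± 585 TPM in T. grandis, with a log2 fold change of -7.61 ± 0.71 (SE; adjusted p = 1.53e-05, limma). In A. argotaenia it stood at 38464 TPM in replicate 2, against 2875 TPM and 5069 TPM in replicates 1 and 3. This contrast changed 50668 features, 22276 higher and 28392 lower in P. chienii. The direction of that balance turned with the scale, since 44.0% were higher with a pseudocount of 1 and 59.8% with a pseudocount of 5. It also turned with the minimum fold, to 64.4% higher among changes of at least 4-fold with a pseudocount of 1. Without 1 P. chienii library and with the filter applied anew, 31697 to 31996 features changed and at most 15.9% of them were higher, against at least 48640 with the tested features kept. Without 1 A. argotaenia or T. grandis library and with the filter applied anew, 51.4% or more were higher.

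Requiring a change against each other species in the same direction left 20342 features higher and 7003 lower in P. chienii than in both. The same rule gave 18139 higher and 1681 lower in A. argotaenia, and 13184 higher and 2129 lower in T. grandis. Both comparisons of P. chienii use the same 3 libraries of it. Simulated unchanged groups gave 0 features higher or lower in both, which the adjusted p gives almost by design when no feature is changed. Independent lists of the observed sizes would share 6686 higher and 6582 lower. Neither value is a baseline for features found in 1 species. The 19111 features detected in P. chienii alone are set against low values in both comparisons, so they tend to be higher in both. The fold changes of both comparisons correlated at 0.677 across features against 0.499 in the simulation, with a covariance of 3.90 against 0.0713. They had the same sign in 64.1% of features, against 66.7% in the simulation, but these percentages cannot be compared. A feature at 0 TPM in P. chienii and in another species has a fold change of exactly 0 there. It counts as without a shared sign, and simulated noise gives no such values. The 3 P. chienii libraries cannot be split into parts of at least 2. Under the spread between these libraries, sharing them gave a covariance of 0.0713. That value argues only against noise of the shared libraries as the main source of the observed 3.90. The P. chienii level itself also enters both comparisons. Simulated unchanged groups cannot tell how much of the covariance comes from that. How much of the overlap count comes from sharing was not measured. As component sums, 7936 components were higher and 3945 lower in P. chienii than in both, and among components above 0 in all 9 libraries 2440 were higher and 1895 lower. Leaving out 1 P. chienii library with the filter applied anew gave 2883 to 3059 features higher than in both, and at least 20082 with the tested features kept.

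Features were finally counted by where they were detected, at 1 TPM or more in all 3 libraries of a species. All 3 species detected 11382 features, which held 58.0% ± 1.28 of the TPM in P. chienii (SD, n = 3), 59.7% ± 1.87 in A. argotaenia and 59.4% ± 1.90 in T. grandis. P. chienii alone detected 19111 features, A. argotaenia alone 17931 and T. grandis alone 12423. These held 32.0% ± 1.29 of the TPM in P. chienii, 18.5% ± 1.19 in A. argotaenia and 16.5% ± 0.904 in T. grandis. Of the features shared by a pair of species alone, 5520 belonged to A. argotaenia and T. grandis, 1872 to P. chienii and A. argotaenia and 1185 to P. chienii and T. grandis. With the other species listed at 0 in all their libraries, 9084 features were found in P. chienii only, 6800 in A. argotaenia only and 5182 in T. grandis only. A detection limit of 5 TPM left 1897, 826 and 769 in the same order. At 1 TPM the counts were 14400 in P. chienii only, 9039 in A. argotaenia only and 7289 in T. grandis only once values under 2% of the highest species mean were set to 0. As component sums 14680 components were detected in all 3 species, and 2685, 2155 and 1397 were found in P. chienii, A. argotaenia and T. grandis only. Among 10670 components of several features detected in all 3 species, the leading feature was the same in A. argotaenia and T. grandis in 65.7%, in P. chienii and T. grandis in 46.3% and in P. chienii and A. argotaenia in 46.2%.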

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

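The form of leaving out a library in which the tested features are kept as with all 9 was chosen after the counts with the filter applied anew had been seen, and both forms are given; leaving out the 3 libraries that stood apart, the term for them, the 2% floor and component sums were also chosen after seeing the data. Over the total counts and the correlations, 276 values under the alternatives stayed within 1.5 times the reported count, or within 1 SD for a correlation, and 75 did not. The separate counts of higher and of lower features and the named results were tallied apart. Of these, 779 values stayed and 81 did not, all 81 of them counts. The named results make up 540 of the 779, so this tally overstates how steady the counts of higher and lower features were. At the feature level all 540 values of the 16 named results kept their direction and passed the test, including all 144 with a library left out and the filter applied anew. These results cover 11 distinct features chosen as the largest changes that passed. Passing under other settings was thus nearly fixed by the choice and adds no support. With the filter applied anew, leaving out a library gave 29356 to 47607 changed features for P. chienii against A. argotaenia, 24257 to 42710 against T. grandis, 20621 to 36211 for A. argotaenia against T. grandis, 31697 to 43073 for P. chienii against the mean of both, and 2883 to 20419 features higher in P. chienii than in both. The cause lies in the filter: without P. chienii replicate 1, for example, 17276 of the 47535 features changed against A. argotaenia were no longer tested. With the tested features kept, the ranges were 46677 to 47665, 41605 to 42565, 35070 to 36335, 48640 to 50608 and 20082 to 20415, and no call changed sign. Over features at 1 TPM or more in all 6 libraries, both forms together gave 4718 to 4997, 4366 to 4618 and 5257 to 5822 for the 3 pairs of species. Features found in P. chienii only, A. argotaenia only, T. grandis only and all 3 species ranged over 9500 to 9927, 7022 to 8168, 5280 to 5955 and 11448 to 11766 with a library left out. Without the 3 libraries and with the filter applied anew, the counts for the 3 pairs, the mean of both and higher than in both were 15083, 14467, 11736, 14658 and 2744.

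In the same order, a pseudocount of 5 gave 24881, 23298, 16909, 21086 and 11569, a mean of at least 5 TPM gave 14099, 13885, 9966, 15355 and 5569, features above 0 in all libraries compared gave 10170, 9576, 9772, 8108 and 2694, component sums gave 21186, 19081, 16671, 21659 and 7936, and components above 0 in all 9 libraries gave 7967, 7898, 6888, 7334 and 2440. The stricter filters and component sums test fewer units by construction. With a pseudocount of 5, a feature at 0 in one species and under 5 TPM in the other cannot reach 2-fold. How much of the lower counts comes from this was not measured. At least 4-fold gave 21969 for A. argotaenia against T. grandis and 24444 for the mean of both, and over features at 1 TPM or more in all 6 libraries 1527, 1463 and 1632, against 7834, 7335 and 8963 with no minimum fold. The mean r within species, P. chienii with A. argotaenia, P. chienii with T. grandis and A. argotaenia with T. grandis was 0.856, 0.0184, 0.0989 and 0.272 by Spearman and 0.962, 0.298, 0.309 and 0.624 over features above 0 in all 9 libraries, and for the pairs of species 0.454, 0.509 and 0.623 as component sums; the cause was not tested. A detection limit of 5 TPM left 1897, 826, 769 and 6333 features in P. chienii only, A. argotaenia only, T. grandis only and all 3 species. The 2% floor gave 14400, 9039 and 7289 in P. chienii only, A. argotaenia only and T. grandis only. In the same order component sums gave 2685, 2155 and 1397, and both together gave 4187, 2792 and 1785.

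The replicate numbers do not pair the libraries: deviations of libraries with the same number correlated between -0.293 and 0.188, and 2 of the 9 libraries correlated best with their own number, a hint from the data and not the design. With the replicate number as a block the counts for the 3 pairs, the mean of both and higher than in both were 47468, 42490, 35954, 50616 and 20289. Depth is unknown, so how far it limits low features cannot be given; count-based tests were not run because the values are TPM.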

Other observations

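In this part the tests of carry-over, of pooling, of shared states and of depth at features of 10 TPM or more were chosen after the results were seen, as was the 2% floor; the bounds for the tests of counterparts and of depth for P. chienii and the counts of splits were set before. The counterpart and P. chienii depth tests were first run with the 2% floor, and then on the features as the report defines them; both values are given. The carry-over test was first run on P. chienii replicates 2 and 1 alone, and then on the pair with the largest median in each species. Under its first bound, a median within 0.5 of 0, the 0.48 of A. argotaenia would go with own related genes; a condition that the levels do not follow single source libraries was added after that value was seen, and the A. argotaenia levels fail it.

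Abundant features of one species were listed at low levels in the libraries of the others. If reads of the receiving species' own related genes were the source, replicates would hold such a feature at like levels, yet at features of another species the log2 ratio of P. chienii replicate 2 to replicate 1 had a median of 2.45, with quartiles of 1.58 and 3.23, and that of T. grandis replicate 3 to replicate 1 a median of -1.45, with quartiles of -2.25 and -0.58, while at own features the medians were -0.03 and -0.11. Both pairs include a library that stood apart, and between P. chienii 2 and 3 and between T. grandis 1 and 2 the medians were -0.84 and -0.48. For P. chienii and T. grandis a transfer of reads between libraries at a rate set by the library is thus a candidate explanation. In A. argotaenia the replicates held P. chienii features at 0.146%, 0.120% and 0.162% and T. grandis features at 0.228%, 0.137% and 0.296%, and the largest median ratio was 0.48, with quartiles of -0.26 and 1.31, as either transfer at like rates or own related genes would give; in 6 of 6 pairs its levels followed source libraries of the group inferred below (A. argotaenia 2 with P. chienii 1, 2 and 3 at 0.750, 0.569 and 0.582), which goes against own related genes, but these cannot be told apart from transfer while a state shared by the grouped libraries stays open.

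P. chienii 1, A. argotaenia 2 and T. grandis 3 stood apart within their species, and the labels give no batch. These 3 libraries may have been pooled or sequenced together, a grouping inferred from the values: in 18 of 18 pairs of receiving library and source species, the levels at foreign features correlated better with source libraries of the same inferred group than with the rest. Over all 75926 tested features the deviations of these libraries from their species means correlated at 0.298, 0.398 and 0.328, above every other pair of libraries of different species (at most 0.242), and with the 2% floor at 0.293, 0.390 and 0.323, whereas at 6333 features of at least 5 TPM in all libraries the values were -0.0078, 0.0817 and 0.178 against a highest other pair of 0.160. These 3 libraries also listed the fewest features above 0 in their species. P. chienii 1 had 45495, against 56827 and 53547 in replicates 2 and 3. A. argotaenia 2 had 53121, against 58665 and 57607 in replicates 1 and 3. T. grandis 3 had 47281, against 54571 and 51456 in replicates 1 and 2. Whether this gives the correlated deviations was not tested. Pooling, a state shared by all 3 samplings and a state of A. argotaenia 2 and T. grandis 3 alone cannot be told apart. The feature sets differ, and a shared state may lie in low features. With the inferred group as a term 47841 features changed between P. chienii and A. argotaenia, and without the 3 libraries 47577 changed with the tested features kept and 15083 with the filter applied anew.

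Many features were detected in a single species. Where a component held 1 feature detected in P. chienii alone and 1 detected in A. argotaenia alone, the levels of these partners correlated at 0.331 over 1503 components (0.338 with the 2% floor), against -0.0728 to 0.0948 in 1000 shuffles of the partners, so such pairs may be counterparts assembled as separate features. The correlation was 0.326 for P. chienii with T. grandis and 0.449 for A. argotaenia with T. grandis, and 58.5%, 57.0% and 65.6% of the features of P. chienii, A. argotaenia and T. grandis alone had a feature detected in another species in their component. Too little depth elsewhere as the whole cause is argued against in P. chienii, where 29.0% of these features averaged at least 10 TPM (29.4% with the floor), and as the cause at that level in each species, where 16.4% of the A. argotaenia and 21.3% of the T. grandis features stood, since every library held at least 99.1% of the features at 10 TPM or more in both other libraries of its species at 1 TPM or more. For features under 10 TPM depth stays open in all 3 species, and so does a true difference in gene content or use, which was not tested since no sequences were used here.

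Other splits of the libraries were counted for each comparison. For P. chienii against A. argotaenia, P. chienii against T. grandis and A. argotaenia against T. grandis, 1 of 10 splits gave as many features, the real one, with real counts of 47535, 42560 and 36039 and a highest other count of 0 in each; 10 splits are too few for a share under 0.05. For P. chienii against the mean of both others, 1 of 100 splits gave as many as the real 50668, and the highest other gave 29047. For features higher in P. chienii than in both others, 1 of 100 splits reached the real 20342, and the highest other gave 19990. The highest other split kept the P. chienii libraries together in both of these counts, as 5 of the 100 splits did, the real one included, and such splits repeat much of the real contrast. Splits that parted these libraries gave at most 20275 and 16664, but they mix species in a group, which widens its spread, so for neither count is it claimed that chance is excluded.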
